A study of Apostichopus japonicus with 9 samples.

How the data were processed

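Total RNA of each animal's intestine was extracted with Trizol, RNA of 18 to 30 nt was taken from a polyacrylamide gel, adapters were ligated to both ends, and products of 140 to 160 bp were sequenced on a HiSeq instrument, per the labels' protocols. The 9 libraries form 3 groups of 3 individuals: control, 6 h and 48 h at 26 °C. The read trimming, the aligner, the reference build, the miRNA database and the counting rules are not given in the sources used here. The miRNA names are those the authors deposited, mostly names from other species, so a name says which known sequence the authors matched and not that this species has the gene. No sequences or genome were used here, and no coordinates are given.

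The authors deposited 1 table for each heat group against the control. Per the file headers, each holds a read count per miRNA for the control and for the heat group, 1 whole number per group. The deposited expression value has no unit in its header. Tested on the values, the authors made it by scaling each library's reads to RPM with the library's total and taking the mean over 3 libraries, with 0.001 for a library at 0. What counts toward that total is not given in the sources used here. The authors' log2 ratio, per the file headers, compares heat with control. On the values it equals the log2 ratio of pooled counts, each divided by its pooled total, with 0.5 in place of a count of 0. The deposited p-value and q-value are the authors' own, from a test that is not named, and 196 p-values at 6 h and 214 at 48 h were entered as 0. The tables list only miRNAs beyond 2-fold, the smallest log2 ratio in size in the authors' deposited table being 1.02 at 6 h and 1.01 at 48 h. The ratios of q to p show that 403 and 415 miRNAs were tested, so 128 and 125 tested miRNAs were not listed and are not analysed here.

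The design written before the data were examined assumed values per library and a test of replicates, with the authors' q-values as the fallback where the tables hold group values only. The tables hold group values only, so the fallback was used: a listed miRNA was called at a q-value under 0.05, and no test was run here. Such q-values compare pooled reads, so they measure counting error and not the spread between the 3 animals of a group. No SD, replicate correlation, principal component or check for duplicate libraries could be had.

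What the pooled columns say about libraries was computed as follows. For a miRNA with reads in 1 library, the pooled count divided by the summed RPM equals the total of that library. The 3 densest values of this ratio in a group were taken as its library totals, without assigning them to particular animals. The sums of these totals gave the constant of the authors' log2 ratio to within 0.0127% at 6 h and 0.0271% at 48 h. A miRNA was assigned to 1 library where count and mean matched a total within the rounding of the mean, and matches to a middle total by chance were expected for fewer than 0.003 miRNAs per group. For the others, the smallest and largest share of 1 library and the smallest coefficient of variation that the count and the mean allow were computed. Where leaving out the library with the most must move a mean by over 1.5 times, the highest mean that the others can have was computed too.

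Among 364 group values from 1 library the smallest library level was 20.01 RPM, and the smallest sum over 2 or more libraries was 40.6 RPM. A 0 was therefore read as less than 20 RPM in every library of a group. A stricter call set every library that could lie below 20 RPM to 0 in the higher group and to 20 RPM in the lower. It asked for a ratio of at least 2. A lower group with reads in 2 or more libraries was taken to have 1 library below 20 RPM. That is the most it can have, and none is known to be. The 20 RPM minimum is inferred from the values. Names of the same number whose counts agreed within 15% in both groups were treated as sharing reads.

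The method was tested on simulated groups, in which the deposited pooled counts were spread at random over 3 libraries with the recovered totals, so it tests the assignment to libraries and not the 20 RPM minimum. All 79 simulated miRNAs with reads in 1 library were recovered in the control, 85 of 85 at 6 h and 84 of 84 at 48 h. Of the miRNAs with reads in more libraries, 0 of 90, 0 of 91 and 0 of 110 were assigned to 1 library. The bounds held for all 169, 176 and 194 simulated miRNAs.

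Named miRNAs followed a rule written before the data were examined: per comparison the 12 largest increases and the 12 largest decreases with at least 10 RPM in the higher group, the 10 most abundant, the listed members of 18 fixed groups, and a short set of families. Others with reads in 2 or more libraries were named after their values were seen, as were the recovered totals and the stricter call chosen. The fixed groups were matched on the miRNA number: muscle, neural, epithelial, sensory and ciliated, endocrine and secretory, blood cell and vertebrate immune, immune-linked and aestivation-linked in this species, stress and ageing, hypoxia, let-7, miR-10, miR-25/92, miR-17, growth restraint, echinoderm-named, protostome-named, and miRNAs the authors predicted. For groups of at least 3 listed members, the median log2 ratio, with ratios against 0 at their bound, was placed among 10000 random lists drawn from the same table within 5 classes of mean level. Levels at 48 h and 6 h were set side by side because both tables hold the same control values. The planned correlation of log2 ratios between the times was not computed, since most ratios are against a 0 and have only a bound. Alternatives were a level of at least 10 RPM, a stricter q-value of 0.01, the 5 most abundant miRNAs left out of the totals, and sums per miRNA number, with others added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.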

Results

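Small RNA was sequenced from the intestine of the sea cucumber Apostichopus japonicus, a bottom-feeding echinoderm whose gut regresses during summer dormancy in warm water. Animals of 100 to 120 g were kept under normal conditions or held at 26 °C for 6 h or 48 h. Each of the 3 groups had 3 libraries. No temperature or sampling time was given for the control in the sources used here. The same control group served both times, so time held and warm water cannot be told apart. The comparisons asked which microRNAs (miRNAs) differ from the control after each time in warm water, and how the times differ from each other. For each heat group the authors tabulated the listed miRNAs with a read count pooled over the 3 libraries of a group and a mean level in RPM, the reads of a miRNA per M reads of its library. Levels below are these authors' means, which carry no SD. Library totals recovered from the counts and means were 91.6, 109 and 145 M reads (M for mega) in the control, 54.4, 69.3 and 96.9 M reads at 6 h, and 57.2, 61.9 and 113 M reads at 48 h.

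The tables listed 275 miRNAs at 6 h and 290 at 48 h, 409 different names in all, each more than 2-fold apart from the control on pooled counts. At this depth counting error was small: the lowest count of a higher group was 1098 reads at 6 h and 1198 at 48 h. The spread between animals is held by the pooled columns only in part. The ratio of a pooled count to the summed RPM shows whether reads came from 1 library or from more, as the plot of this ratio against the library totals displays. All reads came from 1 library for 127 of the 202 listed miRNAs with reads in the control, 119 of 176 at 6 h and 118 of 194 at 48 h. The smallest level of a library behind such a row was 20.01 RPM in depths from 54.4 to 145 M reads, so a listed 0 stands for less than about 20 RPM in every library of a group. Fold values against a 0 are therefore given as at least the mean divided by 20 RPM. Where the lower group had reads in 1 library, its other libraries were set to 20 RPM and the fold is also given as a lower bound. Other folds are ratios of the means.

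**Figure D1:**
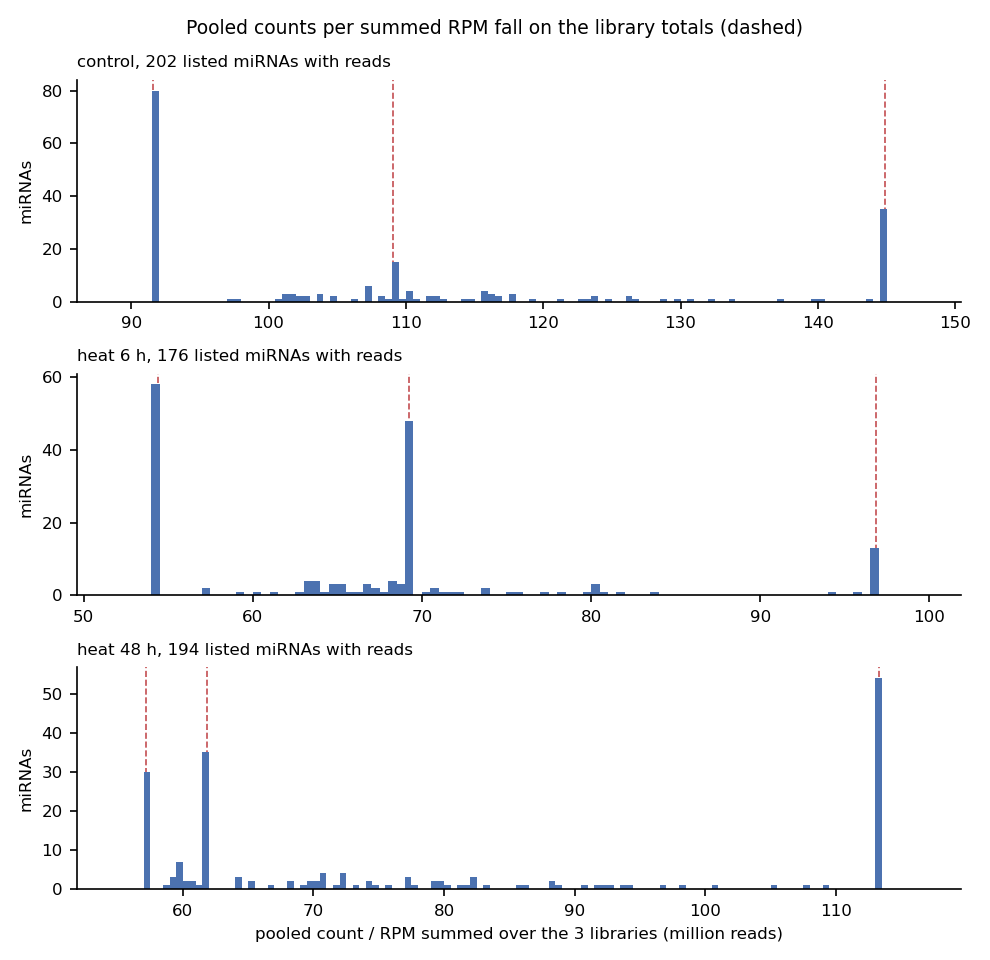
Histograms of the pooled read count divided by the RPM summed over 3 libraries (x axis, in M reads) for the listed miRNAs with reads in the control (202), at 6 h (176) and at 48 h (194), with the y axis in miRNAs and dashed lines at the library totals. The spikes on the dashed lines are mainly miRNAs whose reads all came from 1 library.

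Among miRNAs with reads in both groups, intestines at 6 h in warm water differed most in miR-10c-5p, a member of the miR-10 family that lies in the Hox gene cluster. It had the highest listed level in the control, 127756 RPM, and stood at 97.7 RPM at 6 h, 1307-fold lower. miR-84-5p, whose name belongs to the nematode let-7 family, had 6756 RPM in the control and none at 6 h, at least 338-fold lower. miR-375-3p, known from pancreatic islets and other secretory cells of vertebrates, was 2.65-fold lower at 722 RPM against 1913 RPM. In the other direction miR-4159-3p reached 3280 RPM against 726 RPM, 4.52-fold higher, and miR-71-5p, of a family that acts in stress resistance and lifespan in Caenorhabditis elegans, was 9.90-fold higher at 601 RPM against 60.7 RPM. The far more abundant miR-71c-5p and miR-71, at 9299 and 8884 RPM in the control, were not listed at 6 h. No rise beyond 2-fold was thus listed for these names at 6 h, and a smaller rise in them is not excluded.

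Further miRNAs with reads in 2 or more libraries followed both directions. miR-488-3p was 2.63-fold higher at 2218 RPM, miR-493-3p was at least 10.4-fold higher at 807 RPM and miR-235b-3p at least 10.4-fold higher at 284 RPM. The control reads of miR-493-3p, miR-235b-3p, miR-1587 and miR-4488 came from 1 library each. miR-33a-5p, whose vertebrate relatives lie in the genes of the sterol regulators SREBP, was 3.36-fold higher at 143 RPM, with miR-33a and miR-33-5p judged from their counts to share most of its reads. miR-3620-5p, miR-4466 and miR-4417 were 7.22-, 4.36- and 3.99-fold higher, and miR-1587 and miR-4488 were at least 7.52- and 9.34-fold higher. Without the library with the most, the 380 RPM of miR-1587 at 6 h would be at most 186 RPM. On the lower side, miR-2008-5p, studied in this species in bacterial skin disease, was 4.62-fold lower at 51.6 RPM against 238 RPM, with at least 67.9% of the control level in 1 library and at most 115 RPM on average in the others. miR-37-5p was 4.03-fold lower and miR-25 was at least 3.18-fold lower, with 65.0 RPM in the control and 7.12 RPM, from 1 library, at 6 h. miR-8, the invertebrate relative of the epithelial miR-200 family, had 69.8 RPM in the control, at most 43.6 RPM without the library with the most, and none at 6 h, at least 3.49-fold lower on the mean.

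In the authors' deposited table for 6 h, 156 miRNAs were higher and 119 lower, with q-values up to 2.9e-158. These q-values come from pooled reads and measure counting error, so they do not say whether animals within a group differed as much. For 109 of the higher and 94 of the lower miRNAs, all reads of the higher group came from 1 library. With every library that could lie below 20 RPM set against the call, 81 of the 275 remained at least 2-fold apart. Of these, 46 (28 higher and 18 lower) had reads in 2 or more libraries of the higher group. The least spread between libraries that the columns allow was a coefficient of variation of 61.8% for miR-10c-5p in the control and 11.3% at 6 h. For miR-375-3p it was 47.0% and 3.08%. For miR-84-5p it was 62.1% in the control, with at least 49.2% of the level there in 1 library.

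**Figure D2:**
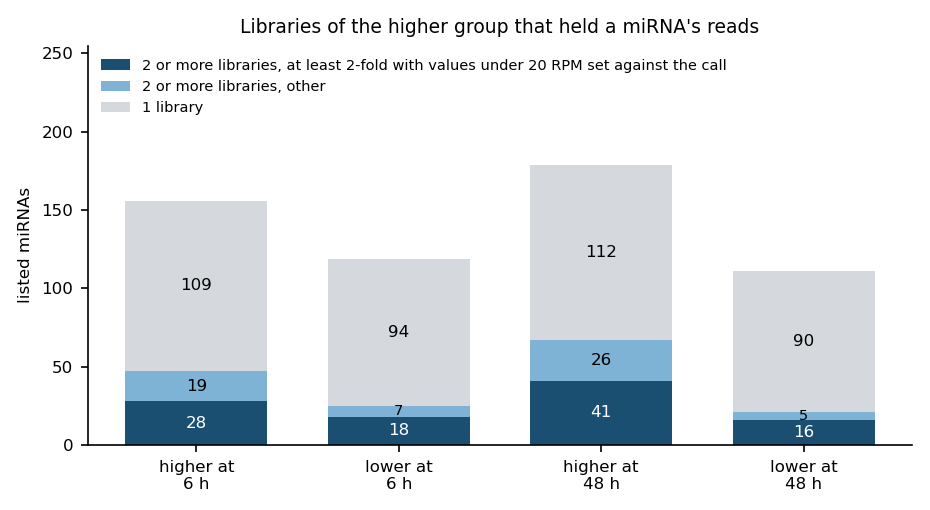
Numbers of listed miRNAs (y axis) that were higher or lower at 6 h and at 48 h, divided by the libraries of the higher group that held their reads. Of the 156 higher miRNAs at 6 h, 109 had reads in 1 library, and of the 179 at 48 h, 112 did.

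The largest changes by the rule for named miRNAs were mostly of this kind. Among the 12 largest increases at 6 h, 8 rested on 1 library, led by miR-5916 at 2740 RPM and miR-4520-5p at 1396 RPM, followed by miR-3961, miR-875-3p, miR-3897-3p, miR-6980-3p, miR-3965 and miR-8065. The remaining 4 had reads in 2 or more libraries and none in the control. They were miR-2a at 229 RPM, miR-5126 at 243 RPM, miR-152b at 95.9 RPM and miR-1621-3p at 110 RPM. At least 82.5% of the level of miR-1621-3p was in 1 library, and the others averaged at most 28.9 RPM. For miR-5126 the share was at least 59.7% and the others averaged at most 147 RPM. Among the 12 largest decreases 8 rested on 1 control library, led by miR-4653-5p at 1056 RPM and miR-9120 at 377 RPM, with miR-7560, miR-33-2-3p, miR-885, miR-7159-3p, miR-4940-5p and novel_mir_97 after them. miR-84-5p, miR-8 and miR-2788-3p had reads in more control libraries, as had let-7d, which had 3375 RPM in the control and none at 6 h, but at least 97.4% of its control level was in 1 library and the others averaged at most 132 RPM.

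Groups of miRNAs fixed before the data were examined are given as members listed. All 6 members linked to aestivation in this species were higher at 6 h, 5 of them with reads in 2 or more libraries. Only 1, miR-92d, was at least 2-fold apart by the stricter call. The stricter ratios of miR-2010, miR-2010-3p and miR-92c-3p were 1.93, 1.94 and 1.98, with 1 control library assumed below 20 RPM. With the 5 most abundant miRNAs left out of the totals, the log2 ratios of miR-2010, miR-2010-3p, which share reads, and miR-92c-3p were 0.80, 0.81 and 0.88, below 2-fold. miR-2010, a name first given in echinoderms, stood at 120 RPM against 55.3 RPM and miR-92c-3p at 70.9 RPM against 29.1 RPM. Among the miR-375 and miR-7 names, the endocrine and secretory group, 3 miR-375 names were lower. miR-375-5p was listed as higher at a mean of 18.0 RPM from 1 library. It did not pass the stricter call, and had a log2 ratio of 0.86 with the 5 most abundant left out. The let-7 group, which includes miR-100 and miR-125 and times development in many animals, had 6 higher and 8 lower members, and 3 higher and 2 lower by the stricter call. Counting names that share reads once leaves 11 of the 14. The group was fixed by number and did not include miR-84-5p. let-7e was 2.58-fold higher at 240 RPM and let-7a-5p 2.71-fold higher at 165 RPM, while let-7j was at least 5.96-fold lower at 13.1 RPM, from 1 library. Its control level of 158 RPM would be at most 74.9 RPM without the library with the most. The immune-linked group had 3 higher and 3 lower members, and 1 of each by the stricter call. miR-210a, of the hypoxia-responsive miR-210 family, had a control mean of 10.04 RPM from 1 library and none at 6 h.

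The echinoderm-named group had 2 higher members, both miR-2010 names, and 1 lower, miR-2008-5p, of which the last passed the stricter call. In the stress and ageing group miR-71-5p and miR-71c-3p were higher and miR-34b-5p lower, the last pair with reads in 1 library, and only miR-71-5p passed the stricter call. The only listed miR-10 member was miR-10c-5p. Tissue markers were sparse at 6 h. The neural group had 2 higher and 2 lower members and the muscle group 1 lower member, miR-133-5p. All had reads in 1 library and a group mean of no more than 37.3 RPM, and none passed the stricter call. The sensory and ciliated group had 3 lower members, each in 1 library and none past the stricter call, and no blood cell or vertebrate immune miRNA was listed. The median of the endocrine group lay at percentile 6.10 of 10000 random lists matched on size and level, and that of the aestivation group at percentile 75.8. The other groups of at least 3 members lay from 7.70 for the authors' predicted miRNAs to 87.7 for the protostome-named group. Names that share reads, such as miR-375-3p and miR-375, were counted separately in all such percentiles, and the 4 endocrine names join to 3.

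At 48 h a set of abundant conserved miRNAs stood higher than in the control. miR-1a-3p, the muscle miRNA, reached 17821 RPM against 7181 RPM, 2.48-fold higher. miR-71c-5p was 2.45-fold higher at 22784 RPM against 9299 RPM, miR-124-3p, which is enriched in neurons, was 2.62-fold higher at 1832 RPM, and miR-125b-5p was 2.49-fold higher at 2530 RPM. The largest ratio among miRNAs with reads in 2 or more libraries of both groups was that of miR-92c-3p, a member of the miR-25/92 family, at 3433 RPM against 29.1 RPM, 118-fold higher. miR-375-3p was again lower, at 669 RPM against 1913 RPM, 2.86-fold, and at most 437 RPM without the 48 h library with the most. By the mean over the 3 groups, with a group whose table does not list the miRNA counted as 0, the 10 most abundant listed miRNAs were miR-10c-5p, miR-71c-5p, miR-71, miR-1a-3p, miR-1-3p, miR-1c, miR-84-5p, miR-4113-5p, miR-4159-3p and miR-125-5p.

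**Figure D3:**
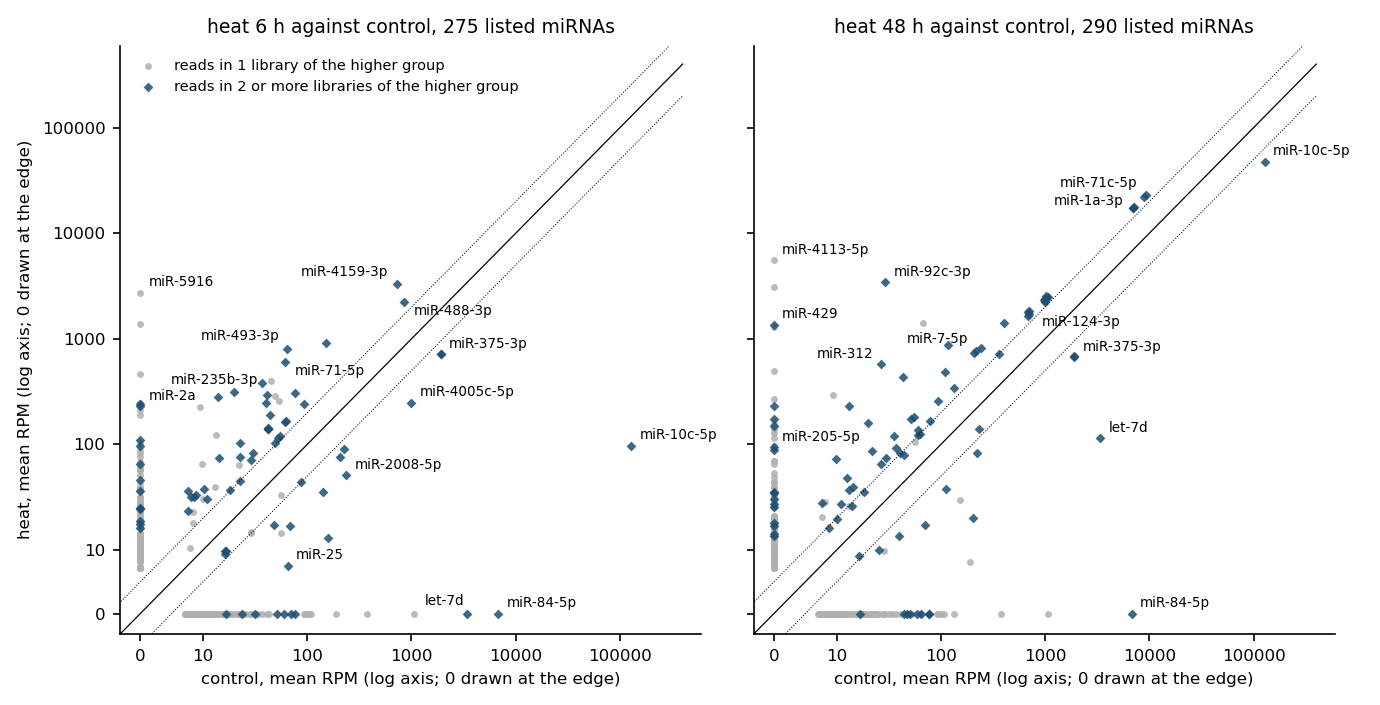
Mean RPM of each listed miRNA in the control (x axis, log scale) and under heat (y axis, log scale), for 275 miRNAs at 6 h and 290 at 48 h, with values of 0 drawn at the axis edge, a solid line at equal levels and dotted lines at 2-fold. Grey points rest on reads in 1 library of the higher group and dark diamonds on 2 or more; miR-10c-5p lies at 97.7 RPM at 6 h and at 47665 RPM at 48 h.

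miR-429, of the epithelial miR-200 family, had 1364 RPM at 48 h in 2 or more libraries and none in the control, at least 68.2-fold higher. miR-205-5p, another epithelial miRNA of vertebrates, had 94.0 RPM against none. miR-7-5p, found in neurons and secretory cells, was 3.49-fold higher at 763 RPM, and miR-312 was 21.5-fold higher at 579 RPM. Lower miRNAs included miR-84-5p, again with none against 6756 RPM, and let-7d, 29.3-fold lower at 115 RPM. That ratio rests on 1 control library, since the other control libraries averaged at most 132 RPM of let-7d. Another miR-84 name, miR-84d-5p, had reads in 1 library at 48 h, at 198 RPM in that library. Whether the same reads changed name was not tested. miR-25 had 65.0 RPM in the control and none at 48 h, at least 3.25-fold lower. miR-10c-5p stood at 47665 RPM, 2.68-fold below the control, but at least 99.91% of that level was in 1 library and the others averaged at most 67.7 RPM. miR-10b was 2.98-fold lower at 37.6 RPM, or at most 16.4 RPM without the library with the most.

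In the authors' deposited table for 48 h, 179 miRNAs were higher and 111 lower, with q-values up to 1.8e-183. All reads of the higher group came from 1 library for 112 of the higher and 90 of the lower miRNAs. With libraries that could lie below 20 RPM set against the call, 89 of the 290 remained at least 2-fold apart. Of these, 57 (41 higher and 16 lower) had reads in 2 or more libraries of the higher group. Several names, such as miR-1a-3p, miR-1-3p and miR-1c, had counts that agreed within 15% and were treated as sharing reads. Joining such names left 31 higher and 15 lower. The least coefficient of variation that the columns allow was 45.1% in the control and 24.7% at 48 h for miR-1a-3p, and 13.5% and 10.6% for miR-92c-3p. It was 27.9% and 36.8% for miR-71c-5p and 13.6% and 32.9% for miR-125b-5p. For miR-124-3p it was 69.7% and 58.2%, and for miR-2004 27.9% and 62.8%. These least values do not rank the true spreads. Up to 93.2% of the 48 h level of miR-124-3p and 95.0% of that of miR-2004 could lie in 1 library. The same limit was 79.7% for miR-1a-3p, 83.0% for miR-125b-5p and 84.5% for miR-71c-5p.

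The named rule again drew mainly on 1 library at 48 h. Among the 12 largest increases 8 rested on 1 library, led by miR-4113-5p at 5595 RPM and miR-71b-5p at 3071 RPM, with miR-4206-3p, miR-5916, miR-7a, miR-8268-3p, miR-4711-3p and miR-8119. miR-429, miR-1903 at 230 RPM, miR-672 at 174 RPM and miR-2207-3p at 149 RPM had reads in 2 or more. Without the library with the most, miR-1903 would be at most 139 RPM and miR-672 at most 108 RPM. Among the 12 largest decreases 7 rested on 1 control library, miR-4653-5p, miR-9120, miR-663a, miR-33-2-3p, miR-885, miR-4940-5p and novel_mir_97. miR-84-5p, miR-2788-3p, miR-4417, miR-2472 and miR-25 had reads in more control libraries.

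All 10 listed neural members were higher at 48 h, from the families miR-124, miR-7, miR-9 and miR-153, 5 of them with reads in 2 or more libraries. By the stricter call 6 miR-124 and miR-7 names were at least 2-fold apart, among which miR-124-3p shares reads with miR-124 and miR-7-5p with miR-7b, and the 10 names join to 7. The muscle group had 5 higher members, all miR-1 names with reads in 2 or more libraries, of which 3 that share reads passed the stricter call, and 2 lower members with reads in 1 library, miR-1 at 53.4 RPM, which also passed the stricter call, and miR-133-5p at 9.32 RPM in the control. All 8 echinoderm-named members, which join to 5, were higher. Those that passed the stricter call were miR-2012-5p at 2384 RPM against 1012 RPM, miR-2004 at 1703 RPM against 701 RPM, miR-2010, and miR-2004-3p and miR-2010-3p, which share reads with them. miR-2006-5p, at 720 RPM against 362 RPM, did not pass it. All 6 aestivation-linked members, which join to 4, were higher, and all but miR-252-5p passed the stricter call, with miR-2010 at 182 RPM. Both epithelial members, miR-429 and miR-205-5p, were higher. The let-7 group had 10 higher and 4 lower members, 5 and 2 by the stricter call, with 5 miR-125 names among the higher and miR-100b-5p lower at 17.3 RPM against 70.4 RPM. The 14 names join to 10. Of the 5 higher names past the stricter call, all but let-7e (miR-125-5p, miR-125b, miR-125b-5p and miR-125c) share reads.

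The endocrine group had 4 higher and 4 lower members at 48 h, and these followed the family: the miR-7 names were higher and the miR-375 names lower. All but miR-375-5p passed the stricter call, and the 8 names join to 6. The 4 listed miR-71 names, the stress and ageing group, were higher and passed the stricter call, miR-71b-5p with reads in 1 library. They join to 3, since miR-71 shares reads with miR-71c-5p. The median of the neural group lay at percentile 88.2 of random lists, that of the echinoderm group at 37.4 and that of the endocrine group at 15.4. Apart from the immune-linked group, the others lay from 8.22 for the authors' predicted miRNAs to 70.8 for the aestivation group. The immune-linked group had 3 members, miR-92c-3p, miR-210a and miR-133-5p, of which the first pair were higher and the last lower, with a median at percentile 99.7. That median is the value of miR-210a, the hypoxia member, which stood at 19.7 RPM, near the minimum, and did not pass the stricter call. Without the library with the most, miR-210a would be at most 11.2 RPM. Both listed blood cell and vertebrate immune members, miR-146b-3p at 70.2 RPM and miR-146a at 11.8 RPM, were higher with reads in 1 library, and the first passed the stricter call. The sensory and ciliated group had 1 higher and 2 lower members, each in 1 library and none past the stricter call, and both miR-10 names were lower. No miR-22, miR-31, miR-137 or miR-200 name was listed at either time. The growth restraint group had 1 member, miR-29b, which was 1.65-fold lower on mean RPM at 141 RPM against 232 RPM and did not pass the stricter call.

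Between 6 h and 48 h, miR-92c-3p showed the largest increase among miRNAs with reads in 2 or more libraries of both heat groups other than miR-10c-5p, from 70.9 RPM to 3433 RPM, 48.4-fold. miR-71-5p, miR-3620-5p, miR-1587 and miR-235b-3p were highest at 6 h and were 4.41-, 3.54-, 4.09- and 10.8-fold lower at 48 h. Of these only miR-71-5p still passed the stricter call against the control at 48 h. miR-493-3p had 807 RPM at 6 h and none at 48 h. miR-2-3p had 248 RPM at 6 h and a mean of 13.6 RPM from 1 library at 48 h, against 39.8 RPM in the control. miR-4005c-5p was lower than the control at 6 h, 249 RPM against 994 RPM, and higher at 48 h, 2254 RPM, with reads in 1 library at 6 h. At 48 h at least 89.2% of its level was in 1 library and the others averaged at most 366 RPM, below the control mean. miR-375-3p and let-7e differed little between the times, at 722 and 669 RPM and at 240 and 261 RPM.

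**Figure D4:**
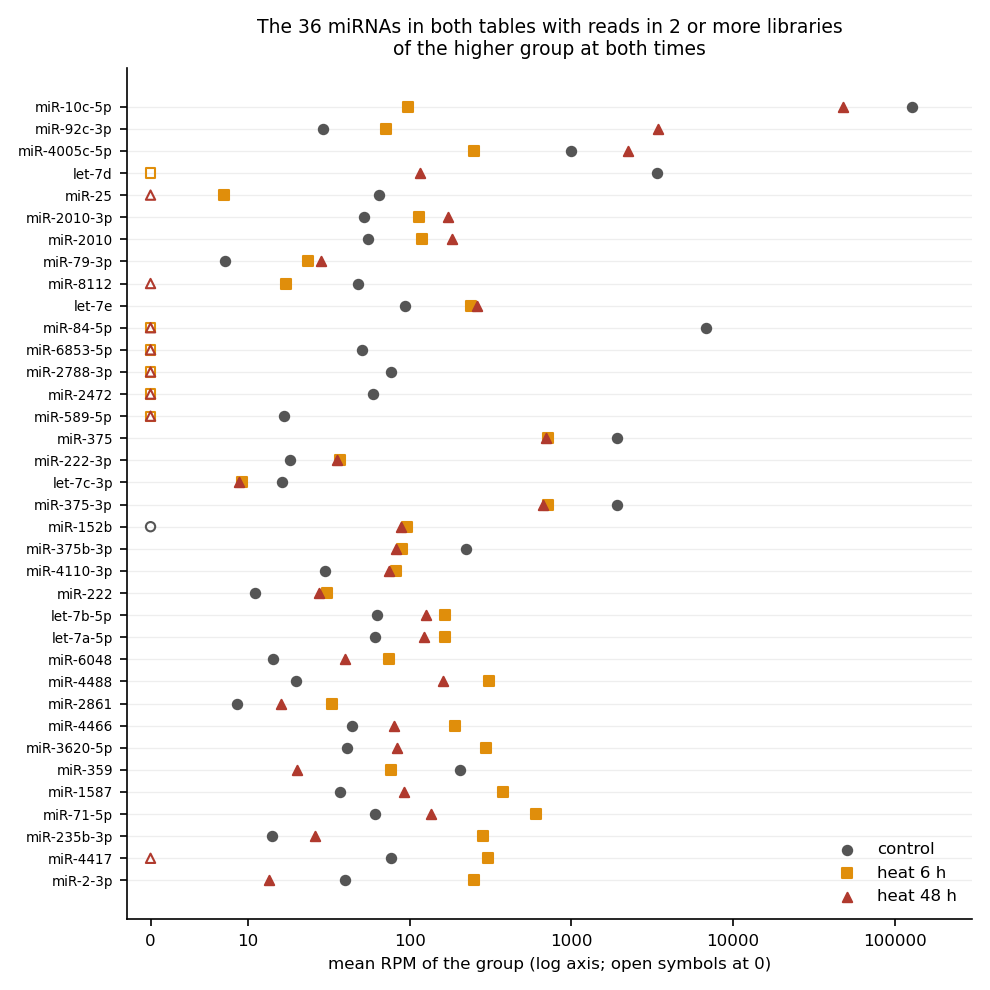
Mean RPM (x axis, log scale, open symbols at 0) in the control, at 6 h and at 48 h of the 36 miRNAs in both tables that had reads in 2 or more libraries of the higher group at both times, 1 miRNA per line, ordered by the ratio of 48 h to 6 h. Of these, 33 lay on the same side of the control at both times. The control libraries are shared, and for miRNAs lower at both times the filter tests the same control libraries, so both favour the same side.

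The tables shared 156 miRNAs, with identical control values in all 156. Of these, 88 were lower at both times, 43 higher at both, 12 lower at 6 h and higher at 48 h, and 13 the reverse. Independent lists drawn from 403 tested miRNAs would share 69.3 higher and 32.8 lower. These are upper limits, because the pool is larger, with 409 names listed in all. The 43 were therefore not shown to exceed such a draw. Of the 88, 76 had no reads in either heat group, and in 71 of the 76 the control reads came from 1 library, which for 45 was the control library of lowest total. Leaving these 76 out, 55 of 80 had the same direction. The 80 still hold miRNAs with none in the control, such as miR-5916, which could only be listed as higher. Part of this agreement was therefore fixed in advance. Both comparisons used the same control libraries, which could not be split, and no test of 48 h against 6 h was possible on pooled values. As values, 40 shared miRNAs lay at least 2-fold apart between the times, 14 higher and 26 lower at 48 h, of which 9 and 15 had reads in 2 or more libraries of the higher group.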

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

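The alternatives that count libraries, ask for reads in both groups, leave out miRNAs at 0 in both heat groups, join names, use mean RPM or use the inferred 20 RPM were chosen after the data were seen; the others were planned. Asking for reads in 2 or more libraries of the higher group left 72 of 275 miRNAs at 6 h (47 higher, 25 lower), 88 of 290 at 48 h (67 higher, 21 lower), and 24 of the 40 that lay 2-fold apart between the times. Asking for reads in both groups left 67 (47 higher, 20 lower) at 6 h and 73 (58 higher, 15 lower) at 48 h. Setting values that could lie below 20 RPM against the call left 81 (52 higher, 29 lower) and 89 (60 higher, 29 lower). Adding the demand for 2 or more libraries left 46 (28 higher, 18 lower) and 57 (41 higher, 16 lower). Of the 131 miRNAs with 1 direction at both times, 55 were left without those at 0 in both heat groups. With reads in 2 or more libraries both times, 33 were left. The 55 include miRNAs at 0 in the control, which could only be listed as higher. Each alternative drops a class of miRNAs by its construction: those with reads in 1 library, those near the minimum, or those at 0 in the other group. The last class includes miR-84-5p and miR-429, which had reads in 2 or more libraries at high levels.

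The counts stayed within 1.5 times at 10 RPM (213 at 6 h, 220 at 48 h), on mean RPM (266 and 279) and with joined names (265 and 275). They also did with the 5 most abundant left out (265 and 283) and with sums per number (237 and 243). The planned q-value of 0.01 removed none and could remove none, since every listed q-value lay far below it. Leaving the listed abundant miRNAs out of the totals shifted every log2 ratio by -0.22 at 6 h, where miR-10c-5p was the only 1 of the 5 listed, and by -0.05 at 48 h, shifts too small to reverse a listed ratio. On mean RPM none of the miRNAs named by the rule with reads in both groups changed direction. No paired analysis was possible because the tables hold 1 pooled value per group. For the same reason other size factors, quantile scaling, other tests, the fit of 9 libraries, pseudocounts, simulated shared controls, other splits of the samples and leaving out a replicate were not run. Set tests that use replicates were not run either, and the percentiles among random lists do not replace them.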

Other observations

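The tests of explanations given here were chosen after the result was seen, as were the miR-143 names, while the groups of miRNAs were fixed in advance. miR-143 and miR-143-3p, smooth muscle miRNAs of vertebrates, were listed with none in the control. They stood at 17.8 and 18.8 RPM in 2 or more libraries at 6 h and at 6.76 and 7.14 RPM in 1 library at 48 h. These means lie below 20 RPM, which a 0 in the control does not exclude, so they give no direction. Neither name passed the stricter call at either time. With 3369 and 3549 reads at 6 h, the names were close in count and are treated as sharing reads. Protostome-named miRNAs, which are not known from echinoderms, included miR-2-3p and miR-2a, higher at 6 h at 248 and 229 RPM in 2 or more libraries each. miR-279b-5p had a control mean of 7.13 RPM from 1 library and none under heat. At 48 h miR-2-3p was also lower and miR-2c-3p had a mean of 25.3 RPM from 1 library. Neither miR-279b-5p nor these 48 h values passed the stricter call. The miR-25/92 group, matched on number only, had 3 higher members and 1 lower at 6 h, 1 of each by the stricter call. At 48 h it had 1 of each by both, where miR-92c-3p and miR-25 went apart. Relatives named under other numbers were not counted, since sequences were not compared. The miR-17 group held 3 miR-92 names at 6 h, 1 past the stricter call, and 1 at 48 h, past it too, all higher. The growth restraint group had miR-34b-5p at 6 h, with a control mean of 8.59 RPM from 1 library and not past the stricter call. The authors' own predicted miRNAs numbered 4 at each time, 2 higher and 2 lower, all with reads in 1 library and 1, novel_mir_97, past the stricter call.

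Listed miRNAs with reads in 1 library made up most of both tables. For values just above the minimum, a per-library minimum of 20 RPM written as 0 may account for the pattern. Of the 364 library levels, 190 lay from 20 to 40 RPM against 77 from 40 to 80 RPM. Levels that thin out upward would give this order too, and the minimum was inferred from the same values, so these counts do not decide it. For higher levels this minimum is argued against as the whole cause, because 78 lay at 100 RPM or more, at least 5 times the minimum. Whether a single library stands apart in each group cannot be told. The library with the most such miRNAs held 63.0% of them in the control, 48.7% at 6 h and 44.9% at 48 h. Each share lies above an even split, and no mark for standing apart was fixed before the data were seen. In the control this was the library of lowest total. Different names for the same RNA in different libraries cannot be told apart from real differences between animals: 18.2% of these miRNAs share their number with another listed name, against 52.5% of the other listed miRNAs, but matches across numbers were not tested without sequences. Individual animals, diet and handling stay open as untested.

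Among listed miRNAs with at least 500 RPM in the control and reads in 2 or more libraries of both groups, 15 names that join to 7 were higher at 48 h, with log2 ratios from 1.06 to 1.62 in the authors' deposited table, and 4, miR-10c-5p, let-7d, miR-375-3p and miR-375, were lower. The 15 were picked for being higher, the listing beyond 2-fold sets the lower end of their ratios, and a response to heat stays open as untested. A fall of the listed lower miRNAs that lifts the rest through the totals is argued against, because leaving these out of the totals shifted the ratios by only -0.145 on the log2 scale, while a fall of RNAs outside the table, 80.2% of the total in both groups, stays open as untested. A scale difference of 2-fold or more common to all miRNAs is also argued against, since 29.3% of the tested miRNAs that were not listed or had reads in both groups, 58 of 198, were listed as higher. Whether 1 library of the 48 h group carries the rise cannot be told apart from a rise in all 3: at least 89.2% of the level of miR-4005c-5p was in 1 library, while for the other names the library with the most held at least 38.1% to 45.5%, uneven to a degree that the columns leave open.

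miR-10c-5p was lower at both times, but at 48 h at least 99.91% of its level was in 1 library, which is consistent with an animal or library close to the control level beside others near none. The same reads moving to another miR-10 name cannot be told apart from a real fall: the other listed miR-10 name, miR-10b, changed by -74.5 RPM at 48 h against a loss of 80091 RPM, but names not listed could hold the rest. At 6 h the loss of 127658 RPM has its counterpart in a gain of 126960 RPM among miRNAs or other reads outside the table, which the fixed sum forces. Sequences and levels per library of all miR-10 names would settle it.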
